A study of Mus musculus with 33 samples.

How the data were processed

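Ribose methylation of mouse ribosomal RNA was measured by RiboMeth-seq in 33 libraries. Per the labels' protocols, whole-cell RNA was extracted from tissue and partly broken down with alkali, which cuts poorly at a ribose that carries a methyl group. Short fragments were purified on gels, linkers were ligated with a modified Arabidopsis tRNA ligase, and the libraries were read on an Ion Proton instrument. The submitters' processing notes name cutadapt 2.0 and Bowtie2 2.3.4.1, with no role given for either. The aligner settings and the source of the rRNA reference are not given in the sources used here, and no genome coordinates were used.

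For each of the 6878 nucleotides of 18S, 28S, 5.8S and 5S rRNA, the authors deposited counts of 5' read ends, of 3' read ends and of their sum in each library, per the file headers. The sum equalled the 5' plus the 3' ends everywhere except at 18S position 106 in the second adult brain library, listed with 0 and 0 ends and a sum of 2608. The listed site nearest to it, SSU-Am99, lay 7 nucleotides away, outside the window of the score. The authors also deposited a fraction methylated per nucleotide and library, the RiboMeth-seq score, together with its mean and standard deviation over the 3 libraries. The deposited fraction was rebuilt from the counts as 1 minus the summed read ends at a nucleotide over a weighted mean of the 6 neighbours on each side. The weights fell from 1 at the nearest neighbour to 0.5 at the farthest, and values below 0 were set to 0. The rebuilt and deposited values differed by at most 5e-10 at the listed sites. A further deposited table gave the authors' mean score per group at 108 sites that they listed as methylated, per the file headers after a correction for barcode effects at some sites. That correction changed 107 of 1188 site means, at 28 sites. Of these, 98 could be rebuilt within 1e-05 by taking the score of 1 or more of the 3 libraries from 5' ends alone. The correction thus left out 3' ends there. As the other 9 could not be rebuilt, the uncorrected score of each library was tested, and the rebuilt corrected score served as an alternative.

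The labels gave 11 groups of 3 libraries, and the series' design text calls the 3 biological replicates. In all 11 deposited sheets the column headers carried the same sample names, those of adult lung. The group of each column was therefore taken from its sheet's name and the replicate from the header's ending. This reading was checked against the authors' table of means: the sheet means equalled those of the group named at 84 to 104 of the 108 sites within 1e-05, and those of any other group at 2 sites at most. Replicate libraries differed by far more than sampling noise, with a chi-square per degree of freedom from 48.9 to 506, and none was treated as a duplicate.

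Depth ranged from 463388 to 35156406 summed read ends per library, with a median of 8896504. The lowest mean count over the neighbours of any listed site was 8.42, in the third E16.5 lung library. A site was tested where that mean was at least 10 in every library, which left 107 sites and removed LSU-Cm3848. In simulated counts the standard deviation of the score from counting alone was at most 0.122 at 50 flanking read ends, 0.063 at 200 and 0.0284 at 1000. These values cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

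Scores were compared with limma 3.58.1 in R 4.3.3, in 1 linear model over all 33 libraries with a mean for each group and moderated variances that followed the mean score. Limma gave 8 contrasts: adult minus E16.5 in brain, heart, kidney, liver and lung, their mean, and E16.5 brain and adult brain each minus E9.5 whole head. It also gave 3 moderated F tests: whether the adult minus E16.5 difference varied between tissues, and whether the 5 adult or the 5 E16.5 tissues differed. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 107 sites of each of the 11 results. A site was called at an adjusted p under 0.05. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

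The design, the rule for naming sites and a first group of other settings were fixed before the data were examined. In each adult minus E16.5 contrast, up to 20 called sites with the largest differences were named, provided that the 3 libraries of one group all lay above the 3 of the other. For the mean contrast the group means had to differ in the same direction in all 5 tissues. The same rule named up to 10 sites in each contrast with E9.5 heads, and each F test named up to 15 called sites with the widest range of group means. Sites called in the same direction in all 5 tissues were also named, as was LSU-Gm4593, on which the study is known to have reported. Sites are named by position in human rRNA, as in the authors' table, with LSU for 28S and SSU for 18S.

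Lists of sites were fixed by rRNA, by nucleotide, by mean score and by whether another listed site lay within 2 nucleotides. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Lists by host gene of the guide snoRNA had also been planned, but the files used here name no guides, so these lists were not built. Guides are given below as background only.

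The same replicate number appeared in every group. The deviations from the group means of same-numbered libraries correlated at 0.655, 0.807 and 0.734 between E16.5 brain and E9.5 head, so the numbers were taken to pair these libraries. In the other 6 contrasts of a pair of groups at most 2 of 3 pairs correlated above 0.1, and the libraries there were not taken as paired. Some of their correlations were strongly negative. The second adult brain library stood at -0.725 with E16.5 brain and at -0.727 with E9.5 head. E16.5 brain and E9.5 head were also the only such pair of groups within 1 library set, as defined below. Groups of a set that were compared only in the F tests or in the tests within sets were not checked for pairing. Those tests took no pairing into account, so a pairing there stays possible.

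That first group of settings comprised the score rebuilt from counts, a logit scale, equal medians of all libraries and other coverage and level minimums. It also held a minimum difference of 0.1, fits to the compared groups only, array weights and no trend in the variance. A replicate block and leaving out each library in turn completed it. The barcode-corrected score, scores from either read end alone and scores with listed neighbours left out of the window were chosen after seeing the data. So were libraries thinned to the shallowest one, leaving out the 5 shallowest libraries and a block with 6 libraries only. Depth as a covariate, a contrast balanced over library sets and tests within library sets were also chosen then. The tests were tried on simulated scores for all 33 libraries, drawn around each site's mean with its spread within groups, and in each of 50 runs 20 of 107 sites were lowered in the adult brain libraries. The adult minus E16.5 brain contrast recovered 26% of changes of 0.05 in score, 52.4% of 0.1, 78.8% of 0.2 and 93.6% of 0.4. In that contrast 4.71% of the calls were false. The simulated scores were independent between sites and between libraries, with no shift of whole libraries, no library sets and no rises. The real scores have such features, so these shares need not hold for them.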

Results

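Ribosomal RNA of vertebrates carries methyl groups on the ribose of many nucleotides, placed by fibrillarin under the guidance of box C/D snoRNAs. The series followed these marks through mouse development. Brain, heart, kidney, liver and lung were sampled from adults and from embryos at embryonic day E16.5, and whole heads from embryos at day E9.5, with 3 biological replicates in each of the 11 groups. The score of a site runs from 0, where no methylation was measured, to 1, where all copies were read as methylated. The authors listed 108 sites, 40 in 18S, 66 in 28S and 2 in 5.8S rRNA, of which 107 could be tested. Averaged over the 33 libraries, 67 sites scored 0.9 or more, 30 scored from 0.75 to 0.9 and 11 from 0.25 to 0.75. These levels rest on the uncorrected score. In the rebuilt barcode-corrected score, LSU-Um3904 averaged 0.877 in place of 0.698 and LSU-Cm1868 0.761 in place of 0.681, above the intermediate level. LSU-Cm4506 averaged 0.961 in place of 0.829. Libraries held from 463388 to 35156406 read ends, and the median count flanking the sites was lowest in the third E16.5 lung library, at 56.96.

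The first comparison asked how adult tissues differed from the same tissues at E16.5, averaged over the 5 tissues with equal weight. LSU-Gm4593, a 28S site at mouse position 4276 whose guide is SNORD78, fell by 0.441 ± 0.0204 (SE), from a mean score of 0.521 at E16.5 to 0.0795 in adults, with 3 libraries per group. SSU-Am576 in 18S rRNA, at mouse position 578 and guided by SNORD93, fell by 0.228 ± 0.0225, from 0.938 to 0.71. Rises were led by SSU-Um354 (mouse position 356, guide SNORD90), which gained 0.38 ± 0.028 to reach 0.911. SSU-Gm436 (position 438, guide SNORD100) gained 0.321 ± 0.046, and SSU-Gm867 (position 869, guide SNORD98) gained 0.306 ± 0.0343. The adjusted p of these 5 sites, from limma, was 1.2e-15 for LSU-Gm4593, 5.23e-09 for SSU-Am576, 1.89e-11 for SSU-Um354, 2.32e-06 for SSU-Gm436 and 4.57e-08 for SSU-Gm867. SSU-Gm1447, 5.8S-Um14, SSU-Cm1272 and LSU-Am4541 rose by 0.269, 0.241, 0.225 and 0.192.

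Of the 107 sites, 39 were higher in adults and 2 lower in the mean over tissues, and 16 of the rises were of 0.1 or more. With the median score of every library set equal, the split was 20 higher and 26 lower, since the median score itself was 0.0335 higher in adults. Equal medians set rises against falls by construction. Of the 26 lower sites, 24 had a mean score of 0.9 or above, with little room to rise. LSU-Gm4593, SSU-Am576, SSU-Um354, SSU-Gm436 and SSU-Gm867 held their direction and call under that setting. From 3' read ends alone 19 sites were higher and 3 lower, and SSU-Gm436, at 0.0739 (adjusted p = 0.436), and SSU-Cm1272, at 0.175 (adjusted p = 0.0604), were not called. The 3' score of 5.8S-Um14 was 1 in every library, so 3' ends could show no difference there. At position 14, this site lies within 15 nucleotides of an rRNA end, where few fragments can be counted on both sides.

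**Figure D1:**
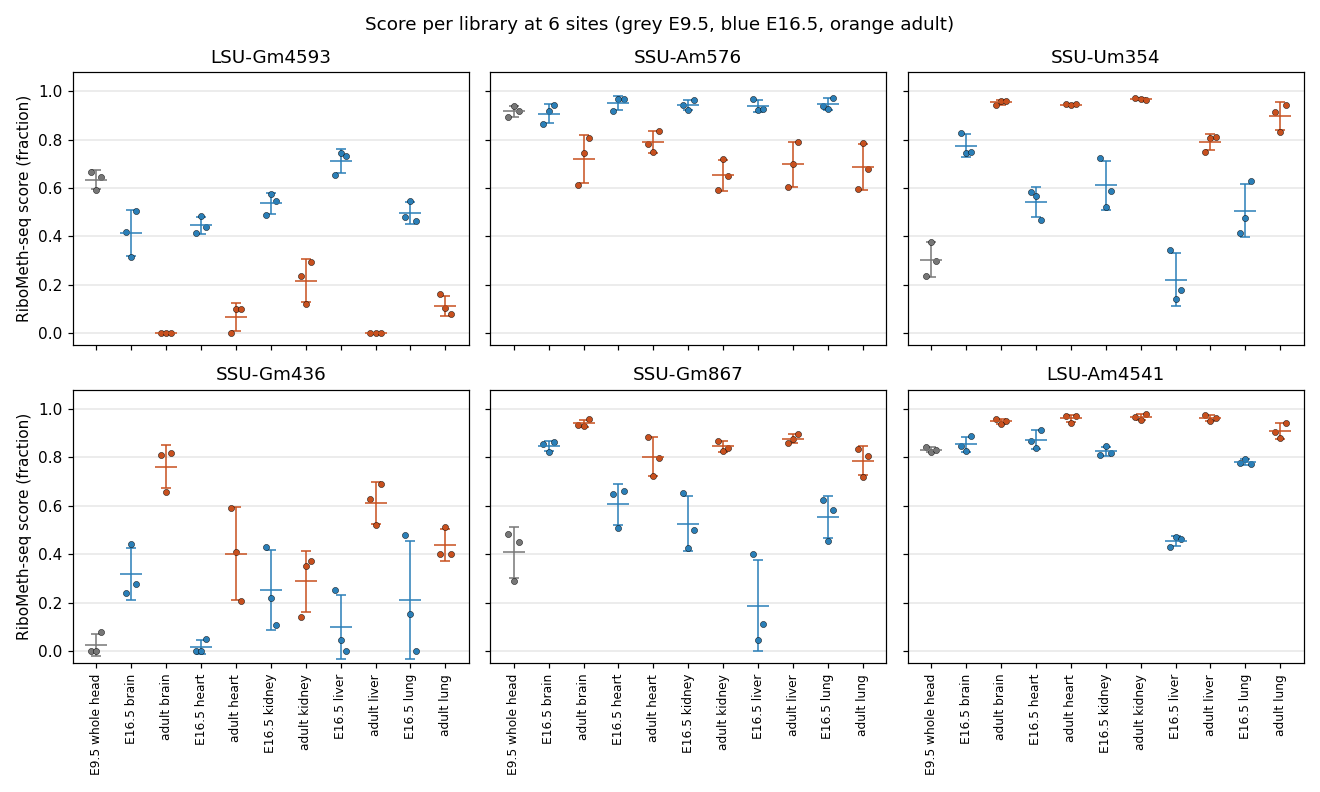
RiboMeth-seq score (vertical axis, 0 to 1, no unit) of each library at 6 sites in the 11 groups, with points for the 3 libraries and bars for the mean and SD. LSU-Gm4593 lay at 0 in all 3 adult brain and all 3 adult liver libraries, while E16.5 liver averaged 0.711; LSU-Am4541 averaged 0.454 in E16.5 liver and 0.963 in adult liver.

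Grouped by molecule, 16 of the 40 tested 18S sites rose, 1 fell and 23 were not called in the mean contrast, against 21, 1 and 43 of the 65 tested 28S sites. Both 5.8S sites rose. By nucleotide, 11 of 20 methylated uridines rose, among them SSU-Um354, SSU-Um1804 and SSU-Um121, and 9 were not called; the list's unadjusted camera p was 0.0393. Of 32 guanosines 15 rose and 1, LSU-Gm4593, fell. Of 22 cytidines 8 rose and 14 were not called, and of 33 adenosines 5 rose and 1, SSU-Am576, fell. By mean uncorrected score, 5 of the 11 sites of intermediate level (0.25 to 0.75) rose and 1 fell. From 0.75 to 0.9, 15 of 29 rose and 1 fell, and of the 67 at 0.9 or above 19 rose. With library medians set equal, 18S sites split into 10 higher and 7 lower and 28S sites into 9 and 19, and 1 of the 5.8S sites was called higher. The adenosines then split into 3 and 12, the cytidines into 2 and 4, the guanosines into 9 and 9 and the uridines into 6 and 1. Sites of intermediate level split into 5 and 1, those from 0.75 to 0.9 into 9 and 1 and those at 0.9 or above into 6 and 24. Sites with a listed neighbour within 2 nucleotides rose in 12 of 22 cases and the others in 27 of 85, with 2 of the latter falling; at equal library medians these became 3 higher and 6 lower against 17 and 20. Adjusted over the list alone, 17 calls were made in 18S, 21 in 28S, 4 among adenosines, 8 among cytidines, 16 among guanosines and 14 among uridines. In the mean and the 5 tissue contrasts, limma's camera called 0 of the 11 lists it could test, with 2 of 66 tests at an unadjusted p under 0.05. Its smallest adjusted p was 0.329, for uridines in kidney, whose unadjusted p was 0.0299, and the smallest with an estimated correlation was an adjusted p of 0.473.

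In brain, LSU-Gm4593 fell from 0.412 ± 0.095 (SD, n = 3) at E16.5 to 0 in all 3 adult libraries, each with at least 1111 read ends per flanking nucleotide on average. A score of 0 is the floor of the measure, so a further fall could not have been read. SSU-Gm436 rose from 0.319 ± 0.107 to 0.762 ± 0.0903, and LSU-Gm3606 from 0.834 to 0.948. SSU-Am576 fell from 0.907 ± 0.04 to 0.722 ± 0.0991. Limma called 6 sites higher and 2 lower; the adjusted p was 2.55e-07 for LSU-Gm4593, 0.00818 for SSU-Gm436, 0.00169 for LSU-Gm3606 and 0.0214 for SSU-Am576. With library medians set equal the split was 2 and 2, and LSU-Gm3606 differed by -0.0276 from 3' ends alone. Without the first, the second or the third adult library 2, 3 and 4 sites were called, and 4 and 5 without the second or the third at E16.5. The call of SSU-Gm436 was lost without the first adult library (0.419) and that of SSU-Am576 without the first (-0.131) or the second (-0.197), or without the second (-0.18) or the third (-0.169) E16.5 library.

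In heart, SSU-Um354 rose from 0.541 ± 0.0623 to 0.945 ± 0.00158 (SD, n = 3; limma adjusted p = 5.18e-05). SSU-Gm436 rose from 0.0161 ± 0.0279 to 0.402 ± 0.191, with an adjusted p of 0.0202. LSU-Gm4593 fell from 0.446 ± 0.0362 to 0.0664 ± 0.0575 (adjusted p = 1.26e-06), and SSU-Am576 from 0.951 to 0.789 (adjusted p = 0.0474). Smaller rises, of 0.0812 and 0.0751, were called at LSU-Cm1327 and SSU-Um121. There were 6 sites higher and 2 lower, or 3 and 1 with library medians set equal. Limma called 1 site, LSU-Gm4593, in a model of the 6 heart libraries alone, 4, 4 and 5 sites without the first, the second or the third adult library and 4 without the first or the second at E16.5. The call of SSU-Gm436 was lost without the first (0.292) or the second (0.383) adult library or either the first or the second E16.5 library (0.378), and the call of SSU-Am576 was lost when any 1 of the 6 was left out, at differences from -0.186 to -0.141.

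In kidney, SSU-Um354 rose from 0.611 ± 0.102 to 0.969 ± 0.00377 (SD, n = 3), SSU-Gm1447 from 0.602 to 0.932 and SSU-Gm867 from 0.526 to 0.845. LSU-Gm4593 fell from 0.537 ± 0.0444 to 0.217 ± 0.0892, and SSU-Am576 from 0.943 ± 0.0196 to 0.653 ± 0.064. LSU-Cm2848 fell from 0.927 ± 0.00771 to 0.851 ± 0.0292; in liver the same site rose by 0.0471 (adjusted p = 0.0105). In all, 9 sites were higher and 3 lower, with limma's adjusted p at 0.000213 for SSU-Um354 and SSU-Am576, 2.54e-05 for LSU-Gm4593 and 0.000241 for LSU-Cm2848. The split was 4 and 9 with library medians set equal, and in a model of the 6 kidney libraries alone limma called 0 sites, with 19 at an unadjusted p under 0.05. SSU-Gm1447 lost its call without the first (0.319) or the second (0.321) adult or the second (0.301) or the third (0.29) E16.5 library.

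Liver had the most called sites of the 5 tissues, 28 higher and 2 lower in adults. LSU-Gm4593 fell from 0.711 ± 0.0492 (SD, n = 3) to 0 in all 3 adult libraries (limma adjusted p = 1.23e-12). LSU-Am4541, at mouse 28S position 4224, rose from 0.454 ± 0.0211 to 0.963 ± 0.0116 (adjusted p = 1.25e-14). SSU-Gm867 rose from 0.186 ± 0.188 to 0.877 ± 0.0183, SSU-Um1442, guided by SNORD61, from 0.36 ± 0.236 to 0.951 ± 0.0405, and SSU-Um354 from 0.222 ± 0.108 to 0.789 ± 0.0338. SSU-Am590, guided by SNORD62, rose from 0.604 to 0.969, and SSU-Am576 fell from 0.94 to 0.698. The split was 13 and 10 with library medians set equal. The rise of SSU-Gm436, 0.514 in the score, was -4.47e-05 from 3' ends alone.

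In lung, SSU-Gm1447 rose from 0.43 ± 0.351 (SD, n = 3) to 0.91 ± 0.0304, SSU-Um354 from 0.507 ± 0.11 to 0.896 ± 0.0583 and LSU-Gm4020 from 0.531 ± 0.0212 to 0.785 ± 0.022. LSU-Gm4593 fell from 0.497 ± 0.0453 to 0.114 ± 0.0419, and SSU-Am576 from 0.947 ± 0.0237 to 0.686 ± 0.0945. Limma called 15 sites higher and 2 lower; the adjusted p was 0.000664 for SSU-Gm1447, 9.06e-05 for SSU-Um354, 0.00169 for LSU-Gm4020, 1.04e-06 for LSU-Gm4593 and 0.000613 for SSU-Am576. At equal library medians the split was 6 and 7, and without the third adult library 11 sites were called. In a model of the 6 lung libraries alone limma called 1 site, LSU-Gm4593. From 3' ends alone 1 site was called, SSU-Um354, and after thinning to the shallowest library 6 were; LSU-Gm4593 stood at -0.227 from 3' ends (adjusted p = 0.128) and kept its call after thinning.

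LSU-Gm4593 and SSU-Am576 were called lower in all 5 tissues and LSU-Am4541 higher in all 5. From 3' ends alone limma called 1 site in brain, 3 in heart, 6 in kidney and 16 in liver, and after thinning 2, 4, 8 and 23. The calls from 3' ends included LSU-Gm4593 in these 4 tissues, SSU-Am576 in kidney and liver and LSU-Am4541 in liver. After thinning LSU-Gm4593 kept its call in all 5 tissues, SSU-Am576 in all except brain and LSU-Am4541 in kidney and liver. At equal library medians LSU-Am4541 differed by 0.0718 in brain and 0.0725 in heart and SSU-Am576 by -0.177 in heart, and these 3 calls were lost, as they were without single libraries. In brain, LSU-Am4541 was not called without any 1 of the adult libraries (0.0903, 0.1 and 0.0943) or the first (0.0914) or the second (0.0814) E16.5 library; in heart, it was not called without any 1 of the adult (0.0822, 0.0964 and 0.0834) or the first (0.0845) or the second (0.0698) E16.5 library. SSU-Um121, SSU-Um354 and SSU-Um1804 were called higher in 4 tissues. In 3 tissues SSU-Um428, SSU-Gm436, SSU-Gm867, SSU-Gm1447, LSU-Cm2352, LSU-Gm2411 and LSU-Gm4464 were called higher. The labels name no batch. The groups were divided into 3 library sets, inferred from whether the authors corrected SSU-Am1031 or SSU-Gm683 for barcode effects. The first set held adult brain and liver. The second held E9.5 head, E16.5 brain and heart and adult kidney and lung. The third held adult heart and E16.5 kidney, liver and lung. The 5 shallowest libraries all lay in the third set, so set and depth overlap. Adult and E16.5 libraries of a tissue always lay in different sets, so no adult minus E16.5 contrast within a set could be had, and stage and set cannot be told apart within a single tissue. In a combination of heart, kidney and lung in which additive set differences cancel, 17 sites were higher and 2 lower, with LSU-Gm4593 at -0.365 ± 0.0279 and SSU-Am576 at -0.219 ± 0.0308.

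**Figure D2:**
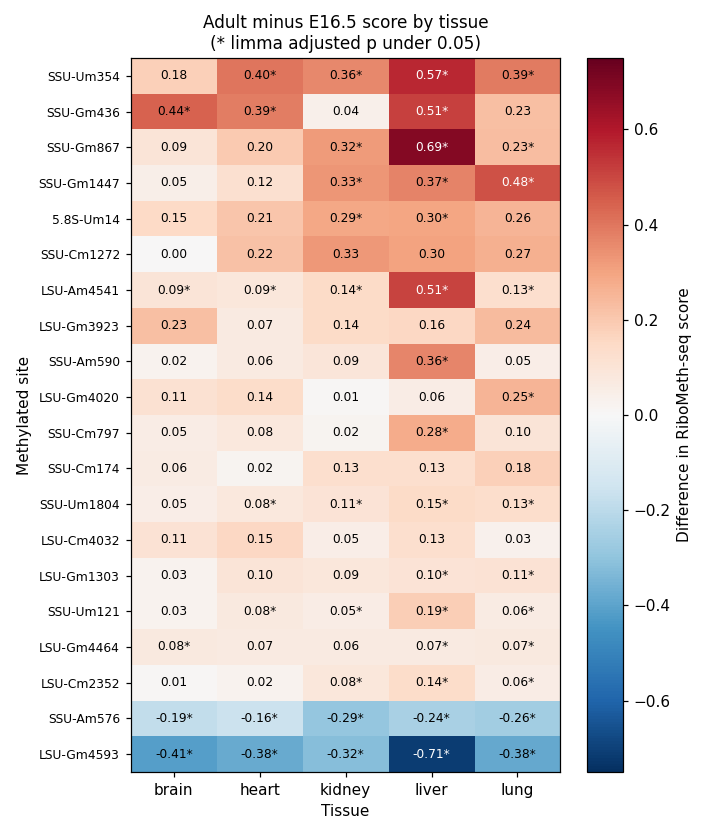
Difference in RiboMeth-seq score, adult minus E16.5, at the 20 sites named in the mean contrast (rows) in the 5 tissues (columns), with the colour scale giving the difference and an asterisk a limma adjusted p under 0.05. LSU-Gm4593 and SSU-Am576 are negative in every tissue, and liver reaches -0.711 at LSU-Gm4593 and 0.691 at SSU-Gm867.

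Whether the adult minus E16.5 difference itself varied between tissues was tested over all 5, and 14 sites passed. LSU-Am4541 rose by 0.508 in liver, 0.143 in kidney, 0.127 in lung, 0.0949 in brain and 0.0873 in heart (F test in limma, adjusted p = 3e-09). SSU-Am590 rose by 0.365 in liver, and its differences elsewhere ran from 0.0239 to 0.09, none of them called (adjusted p of the F test = 2.87e-05). At LSU-Gm4593 the difference was -0.711 in liver, and elsewhere it ran from -0.412 in brain to -0.32 in kidney (adjusted p of the F test = 0.000434). Adult liver and adult brain lay at the floor of 0 in all 3 libraries, so their differences only restate the E16.5 scores. The missing spread at the floor also lowers the pooled spread of LSU-Gm4593, so its p-values in all contrasts may be too small. LSU-Cm2848 ran from -0.0757 in kidney to 0.0471 in liver (adjusted p = 0.000396). Set against the mean of the other 4 tissues, a contrast chosen after seeing the data, liver differed at 13 sites, 12 with a higher and 1 with a lower difference; LSU-Am4541 stood at 0.395 ± 0.029 and SSU-Am590 at 0.308 ± 0.0372. The F test passed 8 sites at equal library medians, and without the first or the second adult liver library 8 and 9 did; 3' ends alone gave 4 and thinning 3. The tissues crossed different library sets between stages; in a combination of the 5 in which additive set differences cancel, 12 sites were called.

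Among adult tissues, limma's F test called 5 sites. SSU-Gm436 was highest in adult brain, at 0.762 ± 0.0903 (SD, n = 3), and lowest in adult kidney, at 0.288 ± 0.127 (adjusted p = 0.0244). LSU-Gm4593 lay at 0 in adult brain and liver, at 0.0664 ± 0.0575 in heart, 0.114 ± 0.0419 in lung and 0.217 ± 0.0892 in kidney (adjusted p = 0.0103). LSU-Cm2848 stood at 0.851 ± 0.0292 in adult kidney and from 0.95 to 0.967 in the other tissues (adjusted p = 4.49e-06). LSU-Um3797 and LSU-Um4468 were lowest in adult lung, at 0.895 and 0.899. At equal library medians limma called 2 sites, and LSU-Um3797, LSU-Um4468 and SSU-Gm436 were not among them. LSU-Gm4593 lost its call without the first (0.208) or the third (0.178) adult kidney library. Without the first adult kidney library 2 were called, and 3 without the third adult kidney, the first or the third adult brain or the second adult lung library; 3' ends alone and thinning to the shallowest library gave 0 in limma, with 7 and 9 at an unadjusted p under 0.05. Tissue and library set were partly confounded, since brain and liver lay in 1 set, kidney and lung in another and heart in the third. Within the sets limma called 0 sites between brain and liver, with 1 at an unadjusted p under 0.05, and 1, LSU-Cm2848, between kidney and lung, with a difference of 0.116 (adjusted p = 1.11e-06). SSU-Gm436 differed by 0.149 within each set and LSU-Gm4593 by 0 and 0.103, none of them called.

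Among E16.5 tissues, 18 sites were called, and liver stood apart at several of them. SSU-Gm867 scored 0.186 ± 0.188 (SD, n = 3) in E16.5 liver and 0.847 ± 0.0219 in E16.5 brain (limma adjusted p = 5.71e-06). SSU-Um354 scored 0.222 ± 0.108 in liver and 0.774 ± 0.0476 in brain (adjusted p = 3.54e-06), and SSU-Um1442 0.36 ± 0.236 and 0.941 ± 0.0299 (adjusted p = 7.92e-05). LSU-Am4541 averaged 0.454 in liver and from 0.782 to 0.874 elsewhere (adjusted p = 2.36e-12). LSU-Gm4593 was highest in liver, at 0.711 ± 0.0492, and lowest in brain, at 0.412 ± 0.095 (adjusted p = 0.000111). In a model of the 15 E16.5 libraries alone 6 sites were called, without LSU-Gm4593; 3' ends alone also gave 6, without LSU-Gm4593, and thinning 11. Brain and heart lay in 1 library set and kidney, liver and lung in another, so the differences between liver and brain mix tissue and set. Among kidney, liver and lung, within their set, limma called 10 sites. The widest differences between their means were 0.414 at SSU-Um1442, 0.389 at SSU-Um354, 0.37 at LSU-Am4541 and 0.368 at SSU-Gm867, and LSU-Gm4593 ranged over 0.214; all 5 were called. Between brain and heart 1 site was called, LSU-Gm3606.

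Between E9.5 whole head and E16.5 brain, which differ in stage and in the tissue taken, SSU-Um354 rose from 0.304 ± 0.072 (SD, n = 3) to 0.774 ± 0.0476 and SSU-Gm867 from 0.408 ± 0.105 to 0.847 ± 0.0219. SSU-Am590 rose from 0.751 to 0.947, LSU-Cm1327 from 0.837 to 0.942 and SSU-Um121 from 0.852 to 0.948. LSU-Gm4593 fell from 0.635 ± 0.0397 to 0.412 ± 0.095 and LSU-Gm3606 from 0.945 ± 0.0268 to 0.834 ± 0.0568. From 3' ends alone limma called 3 sites, all higher; LSU-Gm3606 then differed by -0.00064, LSU-Gm4593 by -0.257 (adjusted p = 0.0842) and SSU-Gm867 by 0.18 (adjusted p = 0.587). Limma called 7 sites higher and 2 lower, with an adjusted p of 8.25e-06 for SSU-Um354, 0.000123 for SSU-Gm867 and 0.00078 for LSU-Gm4593. Both groups lay in the same library set, and with library medians set equal the split was 5 and 3. With the replicate block in a model of these 6 libraries alone limma called 0 sites, with 37 at an unadjusted p under 0.05 and 2 residual degrees of freedom; the block in the model of all libraries gave 12.

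Between E9.5 whole head and adult brain, SSU-Gm436 rose from 0.0259 ± 0.0448 (SD, n = 3) to 0.762 ± 0.0903, SSU-Um354 from 0.304 ± 0.072 to 0.954 ± 0.0099 and SSU-Gm867 from 0.408 ± 0.105 to 0.941 ± 0.0144. LSU-Gm4593 fell from 0.635 ± 0.0397 to 0 in all 3 adult libraries, and SSU-Am576 from 0.916 ± 0.0212 to 0.722 ± 0.0991. In all, 33 sites were higher and 2 lower, with limma's adjusted p at 3.68e-06 for SSU-Gm436, 8.5e-09 for SSU-Um354, 3.08e-11 for LSU-Gm4593 and 0.00622 for SSU-Am576. At equal library medians 6 sites were higher and 7 lower, and from 3' ends alone 5 and 2, without SSU-Gm436 (0.389, adjusted p = 0.0942). These groups lay in different library sets, so stage and set cannot be told apart here. Leaving out the first, the second or the third adult brain library or the third head left 16, 18, 19 and 20 called sites, and the call of SSU-Am576 was lost without the first adult library (-0.14).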

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

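The library sets were defined, and the tests with balanced sets, depth as a covariate, thinned libraries, single read ends and listed neighbours left out were chosen, only after the differences had been seen; the other splits of the samples and equal medians had been planned.

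At 14 sites the adult minus E16.5 difference varied between the 5 tissues in limma's F test. The range of the difference over tissues was 0.604 at SSU-Um1442, 0.597 at SSU-Gm867, 0.421 at LSU-Am4541, 0.391 at LSU-Gm4593 and 0.387 at SSU-Um354. It was 0.341 at SSU-Am590, 0.24 at LSU-Gm2411, 0.157 at SSU-Um121 and 0.148 at LSU-Um2402. At LSU-Gm3606, LSU-Cm2352 and LSU-Cm2848 it was 0.131, 0.125 and 0.123, and at LSU-Cm1327 and SSU-Gm601 it was 0.0762 in each case. Liver had the highest difference at 12 of these sites and the lowest at the other 2, LSU-Gm4593 and LSU-Gm3606. With stage shuffled within tissues, 4 of 100 draws, the real one included, gave 14 sites or more, a share under the 0.05 set for excluding chance, and the highest other draw gave 22. Such draws split the common stage effect unevenly between tissues, so they are not free of real differences.

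Outside the listed sites, 69 nucleotides scored 0.75 or more in all 3 libraries of at least 1 group. Of these, 13 lay within 15 nucleotides of an rRNA end, where few fragments can be counted on both sides. At most of the other 56 the read ends disagreed: the mean scores over 33 libraries from 5' and from 3' ends lay more than 0.2 apart at 36, with a median gap of 0.297. At 28S C662 they were 0.947 and 0.427. Both reached 0.75 at 3 positions, among them 28S C771 at 0.814 and 0.817; these examples were picked after their values were seen. These positions were not tested as sites.

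The first pattern is that more sites rose than fell from E16.5 to adult. Additive library sets are argued against by the balanced contrast, with 17 sites higher and 2 lower, and a linear effect of depth by a model with the log10 median flanking count of each library as a covariate, with 36 higher and 2 lower. A shift of whole libraries stays open. With equal medians 20 sites were higher and 26 lower, the outcome foreseen for such a shift. That outcome was largely fixed, since equal medians set rises against falls by construction. Of the 26, 24 had a mean score of 0.9 or above, with little room to rise. The setting would also remove a real general rise, so a shift and such a rise cannot be told apart. The count of 41 was matched by 1 of 100 draws with stage shuffled within tissues, the real one, with 13 as the highest other, which excludes chance. Developmental stage, which the design names, stays open and was not tested separately.

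The second pattern is the fall of LSU-Gm4593 and SSU-Am576 while most called sites rose. In the balanced contrast the smaller of the falls was -0.219, and from either read end alone the smallest was -0.212, so neither additive sets nor a bias at 1 read end can be the whole cause. LSU-Gm4593 has 2 listed neighbours in its score window, and without them it differed by -0.391 ± 0.026; SSU-Am576 has 0, so that test rests on LSU-Gm4593 alone, as was settled after both values had been seen. Developmental stage stays open here too and was not tested separately from library sets that act differently on each tissue.

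The third pattern is the number of calls in liver. In a combination of the 5 tissues that is 0 under additive set effects and a common stage effect, 12 sites were called. Additive sets with a common stage effect thus do not account for the 5 tissues together. The combination also leaves 0 when a tissue other than liver departs, so it cannot decide on liver alone. After thinning, liver had 23 called sites and the next tissue 8, which argues against unequal depth as the whole cause. Leaving out the 5 shallowest libraries raised the counts in kidney and brain. It also removed the first and the third E16.5 liver libraries, so it cannot decide on the liver count. A stage difference particular to liver stays open and was not tested separately.

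For the contrasts of 3 libraries with 3, the 10 splits are too few for a share under 0.05. They ignored the pairing of E16.5 brain with E9.5 head by replicate number. The real split alone, 1 of 10, reached its count in each: 8 in brain, 8 in heart, 12 in kidney, 30 in liver and 17 in lung, 9 between E9.5 head and E16.5 brain and 35 between E9.5 head and adult brain. The highest other split had 1 called site in lung and 0 by limma in the rest. Among adult tissues, 1 of 100 draws gave 5 or more sites, with 2 as the highest other. Among E16.5 tissues 2 of 100 gave 18 or more, with 27 as the highest other. Both shares are under the 0.05 set for excluding chance, although a shuffled draw of the E16.5 libraries exceeded the real count.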

How the results depend on the processing

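The barcode-corrected score and the settings with single read ends, listed neighbours left out of the score window and thinning were chosen after seeing the data. So were leaving out the 5 shallowest libraries, the block with 6 libraries, depth as a covariate, balanced sets and tests within sets. The 5 shallowest were E16.5 lung 3, adult heart 3, E16.5 liver 1 and 3 and E16.5 kidney 2. Without them E16.5 liver held 1 library, and its spread came from the other groups. The score rebuilt from counts, the filter at a mean score of 0.2 and the absence of a flanking minimum changed none of the 136 calls at named sites; the barcode-corrected score and the variance without a trend each ended 1 and turned 0 around. Equal medians ended 47 and turned 1, LSU-Am4493 in brain, to -0.00314. Scores from 3' ends alone ended 83 and turned 2, LSU-Gm3606 in brain (-0.0276) and SSU-Gm436 in liver (-4.47e-05). At the sites that the authors corrected for barcode effects, 3' ends are what their correction, as rebuilt, left out in some libraries. LSU-Gm3606 and SSU-Gm436 were not among the corrected sites. Nor were LSU-Gm4593, SSU-Am576, SSU-Um354, SSU-Gm867 and LSU-Am4541, so the correction did not touch any of these. Thinning and models of the compared groups alone each ended 52, a minimum difference of 0.1 ended 30, scores from 5' ends alone 21, a logit scale 12, leaving out the 5 shallowest libraries 7, listed neighbours left out of the window 6, array weights 3, and leaving out 1 library at a time 207 of 1812. A minimum of 100 flanking read ends ended 0 of the 44 it could test in limma. The block with 6 libraries ended 9 of 9, balanced sets 4 of 20 and depth as a covariate 1 of 20. Within sets, 5 of 5 ended for adult brain and liver, 4 of 5 for adult kidney and lung, 14 of 15 for E16.5 brain and heart and 6 of 15 for E16.5 kidney, liver and lung. The replicate block in the model of all libraries ended 0 of the 136 in limma and moved no count by more than 1.5 times, giving 8 in brain, 10 in heart, 17 in kidney, 40 in liver, 19 in lung, 12 in E16.5 brain against head, 42 in adult brain against head, 46 in the mean, 15 in the tissue F test, 6 in adult tissues and 23 in E16.5 tissues. Between E16.5 brain and E9.5 head all 6 libraries correlated best with their own number; in the other contrasts at most 3 of 6 did. Depth limits the sites with fewest flanking read ends, and the cause of the changes was not tested, except that a minimum count or difference leaves fewer sites to call and thinning leaves fewer reads.

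Counts of called sites that moved by more than 1.5 times, against 8 in brain, 8 in heart, 12 in kidney, 30 in liver, 17 in lung, 9 in E16.5 brain against head, 35 in adult brain against head, 41 in the mean, 14 in the tissue F test, 5 in adult tissues and 18 in E16.5 tissues, were as follows. A logit scale gave 20 in brain, 47 in liver, 62 in adult brain against head and 27 in adult tissues. Equal library medians gave 4 in brain, 4 in heart, 13 in adult brain against head, 8 in the tissue F test and 2 in adult tissues. A minimum of 100 flanking read ends, which left 23 sites to test, gave 3 in brain, 2 in heart, 5 in kidney, 9 in liver, 6 in lung, 4 in E16.5 brain against head, 6 in adult brain against head, 13 in the mean, 5 in the tissue F test, 1 in adult tissues and 6 in E16.5 tissues. A minimum difference of 0.1 gave 5 in brain, 4 in heart, 18 in liver, 11 in lung, 18 in adult brain against head, 18 in the mean and 3 in adult tissues. Models of the compared groups alone gave 16 in brain, 1 in heart, 0 in kidney (limma, 19 at an unadjusted p under 0.05), 1 in lung, 57 in adult brain against head, 13 in adult tissues and 6 in E16.5 tissues. Array weights gave 26 in brain, 19 in kidney, 48 in liver, 16 in E16.5 brain against head, 57 in adult brain against head, 25 in the tissue F test and 31 in adult tissues. Scores from 5' ends alone gave 5 in brain, 15 in heart, 21 in kidney, 62 in liver, 26 in E16.5 brain against head, 62 in adult brain against head, 67 in the mean, 22 in the tissue F test, 10 in adult tissues and 33 in E16.5 tissues. Scores from 3' ends alone gave 1 in brain, 3 in heart, 6 in kidney, 16 in liver, 1 in lung, 3 in E16.5 brain against head, 7 in adult brain against head, 22 in the mean, 4 in the tissue F test, 0 in adult tissues (limma, 7 at an unadjusted p under 0.05) and 6 in E16.5 tissues. Thinning to the shallowest library gave 2 in brain, 4 in heart, 6 in lung, 3 in the tissue F test, 0 in adult tissues (limma, 9 at an unadjusted p under 0.05) and 11 in E16.5 tissues. Leaving out the 5 shallowest libraries gave 14 in brain, 29 in kidney, 17 in E16.5 brain against head, 55 in adult brain against head and 8 in adult tissues. The replicate block in a model of 6 libraries gave 0 in E16.5 brain against head (limma, 37 at an unadjusted p under 0.05). The contrast balanced over library sets gave 19 in the mean. Within library sets, with fewer groups to compare, adult tissues gave 0 for brain and liver (limma, 1 at an unadjusted p under 0.05) and 1 for kidney and lung, and E16.5 tissues gave 1 for brain and heart and 10 for kidney, liver and lung. At a score of 0.9 in place of 0.75, 9 positions outside the listed sites remained of 69, by construction fewer.

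Leaving out 1 library at a time gave 2 to 8 in brain, 4 to 6 in heart, 8 to 18 in kidney, 25 to 28 in liver, 11 to 21 in lung, 8 to 10 in E16.5 brain against head, 16 to 28 in adult brain against head, 36 to 51 in the mean, 8 to 18 in the tissue F test, 2 to 6 in adult tissues and 16 to 23 in E16.5 tissues. The libraries that moved a count by more than 1.5 times were adult brain 1 (2), adult brain 2 (3), adult brain 3 (4), E16.5 brain 2 (4) and E16.5 brain 3 (5) for brain. For heart they were adult heart 1 (4), adult heart 2 (4), adult heart 3 (5), E16.5 heart 1 (4) and E16.5 heart 2 (4). For lung it was adult lung 3 (11). For adult brain against head they were adult brain 1 (16), adult brain 2 (18), adult brain 3 (19) and E9.5 whole head 3 (20). For the tissue F test they were adult liver 1 (8) and adult liver 2 (9). For adult tissues they were adult brain 1 (3), adult brain 3 (3), adult kidney 1 (2), adult kidney 3 (3) and adult lung 2 (3).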

Other observations

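In the brain series the median score per library was 0.917 ± 0.00873 (SD, n = 3) in E9.5 head, 0.948 ± 0.00598 in E16.5 brain and 0.971 ± 0.00118 in adult brain. Adult lung had a median of 0.934 ± 0.00517 and adult liver 0.967 ± 0.00467. The E16.5 groups ran from 0.894 ± 0.0343 in lung to 0.948 ± 0.00598 in brain. These medians were not tested as such.

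Of the 41 sites called in the mean contrast, 39 were also called with the same sign from 5' ends alone and 20 from 3' ends alone. The 3' score of 5.8S-Um14 was 1 in every library, so its rise of 0.241 was seen at 5' ends only. LSU-Gm3606 differed by -0.111 between E9.5 head and E16.5 brain and by 0.115 between E16.5 and adult brain, and its difference from 3' ends alone was -0.00064 in the first case and -0.0276 in the second.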
